A study of Homo sapiens with 2 samples.

How the data were processed

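The assay was hMeDIP-seq, in which DNA fragments that carry 5-hydroxymethylcytosine (5hmC, the oxidation product of 5-methylcytosine made by TET enzymes) are pulled down with an antibody and sequenced. Per the labels' protocols, primary human vascular smooth muscle cells were starved in 2.5% serum for 24 hours and then kept in 50 nM rapamycin, an mTOR inhibitor, for 48 hours. DNA was sheared to 200 to 500 bp and 1 µg was immunoprecipitated. The labels name the cells as aortic in the cell type field and as coronary artery in the growth protocol, and this difference could not be settled. There was 1 immunoprecipitated (IP) library and 1 input library, with n = 1 each, and both came from rapamycin-treated cells. No untreated library was analysed here, so no effect of rapamycin can be measured from these values, and no difference has a replicate check.

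The authors deposited 1 table of peaks. Bowtie2, MACS2 and ChIPseeker and the genome build hg38 are named in the submitters' processing notes, and their versions and parameters are not given in the sources used here. Per the file headers, each peak has a fold enrichment (a ratio of IP over background), a −log10 p-value, a −log10 q-value, a summit position, an annotation class, an assigned transcript and a distance to its transcription start site (TSS). The deposited score column is the whole part of 10 times −log10 q and was not used further. The lowest deposited −log10 q was 1.31, just above the value of a q of 0.05. Peak names ran to 4934 and the table held 4889 peaks, so 45 numbered peaks were not analysed here. Starts in the deposited table counted from 0 and were changed to count from 1. All fold enrichments and significance values of peaks are the authors' own and were used only to describe, rank and filter this list.

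Read counts per library are not in the table, so the depth of each library is unknown. The number of fragments behind each peak was solved from the deposited fold and p-value. Fold was taken as (pile-up + 1)/(background + 1) and p as the Poisson probability of more than the pile-up, and every whole pile-up was tried. The other tail, the probability of at least the pile-up, was tried too and did not match the deposited values. Both were tried after seeing the table. For all 4889 peaks a whole number matched the deposited −log10 p within 0.0003, and the next best whole number missed by at least 0.00193. On simulated peaks the solver returned the true pile-up for 100% of 387. Simulated peaks with a low pile-up relative to their background were left out. Recovery at the lowest folds, such as those on the mitochondrial genome, was therefore not tested this way. The 95% intervals given for a peak's fold come from the exact Poisson interval of its pile-up and cover counting error of the IP only.

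Shares of peaks carry Wilson 95% intervals, and counts of peaks carry exact Poisson 95% intervals. Peaks are not replicates, so no p-value is given. Annotation classes and TSS distances were taken from the authors' table. Gene spans came from a RefSeq gene table of GRCh38.p14, the same build as hg38. It holds no strand, so TSS positions could not be rebuilt. Of 3382 assigned gene names, 3178 matched a symbol or a unique older symbol in it. Autosomal peak midpoints were compared with 1000 random placements of the same widths between the first and the last gene of the same chromosome. Assembly gaps were not known and were not removed, which leaves some random positions in gaps. A placement within 50 kb of each peak served as the local comparison.

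A total of 15 gene lists with 437 genes were fixed before the data were examined. For each, the number of members with a peak was compared with 10000 random lists of the same size drawn from 19974 protein-coding genes in the same decile of gene length. Where 32 long genes were simulated with no enrichment, 1% of lists fell in the top 2.5% of length-matched lists, and 51% did so without matching. The simulation placed peaks in proportion to gene length, a stronger dependence than in these data. Here the share of genes with an assigned peak rose from 5.06% in the shortest decile to 11.6% in the longest (4.35% to 20.9% by position). The 51% therefore does not measure the bias in these data. The share of random lists reaching the observed number describes this peak list and is not a p-value. Peaks were linked to genes by the authors' assignment (main) or by a midpoint inside the gene span with 3 kb margins on either side (alternative).

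The genes named were chosen by a rule fixed in advance. It took the genes of the 10 highest-fold peaks on chromosomes 1 to 22 and X, of the 10 highest-fold peaks within 1 kb of a TSS, the 10 genes with most assigned peaks, and up to 4 members per list with the highest-fold peak. Genes named because a peak lies inside their span, and list members named as having no peak, were chosen after the values were seen. The values of 1 member that the rule would name are not reported here. Alternatives fixed in advance were stricter thresholds by −log10 q or fold, merging of peaks within 1 kb, removal of unplaced sequence, removal of the 1% highest folds, other promoter widths and other list matching. Alternatives by solved background and pile-up, the comparison of gene spans with random placements, and everything on chromosome ends were chosen after the data had been seen. The same holds for the limits of 2 and 10 fragments of background, a pile-up of 10, zones of 5 Mb, the first 14 Mb of chromosome 21, 3-fold, and the range of 80% to 100% of the pile-up ceiling. GC content, CpG density and tandem repeats in peaks were planned and not run, because no genome sequence was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.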

Results

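Genome-wide 5hmC was mapped in human vascular smooth muscle cells after 48 hours in 50 nM rapamycin, a treatment meant to raise hydroxymethylation by TET2. The data consisted of 1 IP library compared with 1 input library. The comparison asks where in the genome IP fragments exceeded the input. It holds no untreated cells and no replicate.

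The authors' peak list held 4889 regions of 5hmC enrichment that together covered 889 kb. Of these, 4459 (91.2%, Wilson 95% interval 90.4 to 92.0) lay on the autosomes. The regions were short, with a median width of 142 bp, quartiles of 109 and 197 bp and 15 regions over 1000 bp. A total of 1094 peaks (22.4%, 21.2 to 23.6) had the minimum width of 106 bp. The median fold enrichment was 5.11 (quartiles 4.42 and 5.87), the range was 1.55 to 16.99, and 21 peaks exceeded 10-fold. The fragments behind each peak were few: the solved IP pile-up at the summit had a median of 9 (quartiles 7 and 12, minimum 5), against a median background of 0.796 fragments. A total of 1358 peaks (27.8%, 26.5 to 29.0) rested on 7 fragments or fewer. The lowest background, 0.533 fragments, was shared by 794 peaks (16.2%), among them those of MYL9, HEY2, NOTCH3 and KDM5A named below. The folds of these peaks follow the IP pile-up alone, so equal pile-ups gave equal folds. Counting error at low pile-ups was wide: 9 fragments at the peak upstream of MYL9 gave a fold of 6.52 with a 95% interval of 3.34 to 11.8.

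**Figure D1:**
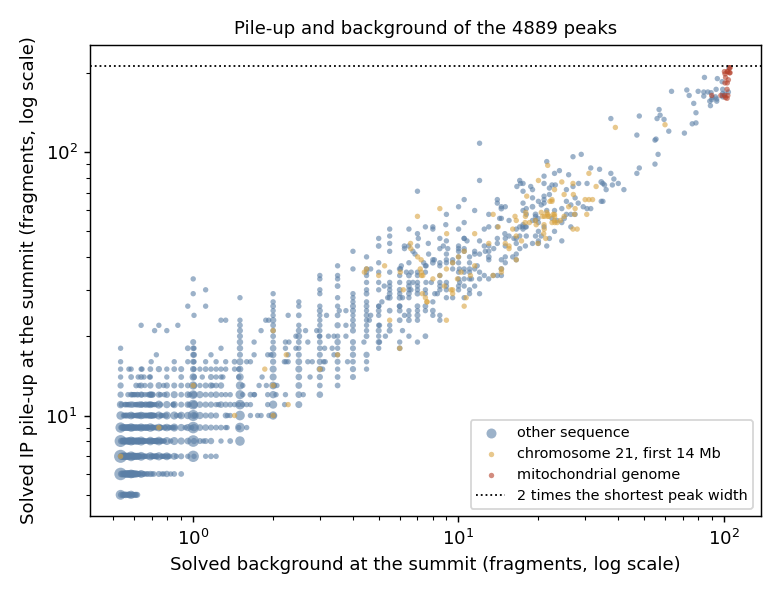
Solved IP pile-up (y axis, fragments, log scale) against solved background (x axis, fragments, log scale) for all peaks, with point size growing with the number of peaks at that pair of values and a dotted line at 212 fragments, 2 times the shortest peak width. Mitochondrial peaks (red) lie at 160 to 209 fragments, and peaks of the first 14 Mb of chromosome 21 (yellow) had a median background of 15.02 fragments against 0.759 on the autosomes.

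The highest enrichment lay outside promoters. The strongest peak, on chromosome 13 (hg38) from 113876168 to 113876345, was enriched 16.99-fold (95% counting interval 11.8 to 23.7, 33 fragments). It lay downstream of a gene and was assigned to the noncoding RNA gene LINC00454. The next peaks were intergenic and were assigned to LOC105376297 on chromosome 9 (14.99-fold, 10.2 to 21.3), PNMA6E on chromosome X (14.7-fold, 10.0 to 20.7), LOC107984862 on chromosome 16 (14.1-fold, 9.03 to 20.96) and RPEL1 on chromosome 10 (13.8-fold, 9.20 to 19.99). Among the first 10, 4 lay in introns. CASZ1, a zinc-finger transcription factor gene, held a peak in intron 2 (chromosome 1, 10744420 to 10744693) of 13.2-fold (8.48 to 19.7). CDH4, which encodes a classical cadherin, held one in intron 2 (chromosome 20, 61283341 to 61283581) of 12.8-fold (8.51 to 18.5). PRKAG2, which encodes a regulatory subunit of AMP-activated protein kinase, held one in intron 1 (chromosome 7, 151854982 to 151855640) of 12.4-fold (8.15 to 18.3). The peak in intron 19 of ADGRB1, an adhesion G protein-coupled receptor gene, was assigned to the pseudogene MROH4P, 55.3 kb away (12.8-fold, 8.16 to 19.3). The last of the 10, assigned to LOC105374115 on chromosome 3, was intergenic (12.4-fold, 7.61 to 19.2). The lower limit of the first (11.8) lay below the estimate of the last (12.4), so the order among the 10 is not resolved.

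Introns held the most peaks, with 1766 of 4889 (36.1%, 34.8 to 37.5). Distal intergenic sequence followed with 1514 (31.0%, 29.7 to 32.3) and promoters, within 3 kb of a TSS, with 1250 (25.6%, 24.4 to 26.8). Exons held 232 peaks (4.75%, 4.18 to 5.38), downstream regions 72, 3′ UTRs 50 and 5′ UTRs 5. The median distance from a peak to its assigned TSS was 9.89 kb (quartiles 2.90 and 25.3 kb). Within 1 kb of the TSS lay 672 peaks (13.7%, 12.8 to 14.7), and a further 578 (11.8%) lay at 1 to 3 kb. Peaks at 10 to 100 kb were the largest group, with 2257 (46.2%, 44.8 to 47.6). The shares of the genome in these classes and distances were not computed, so no preference for any of them can be read from these values.

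**Figure D2:**
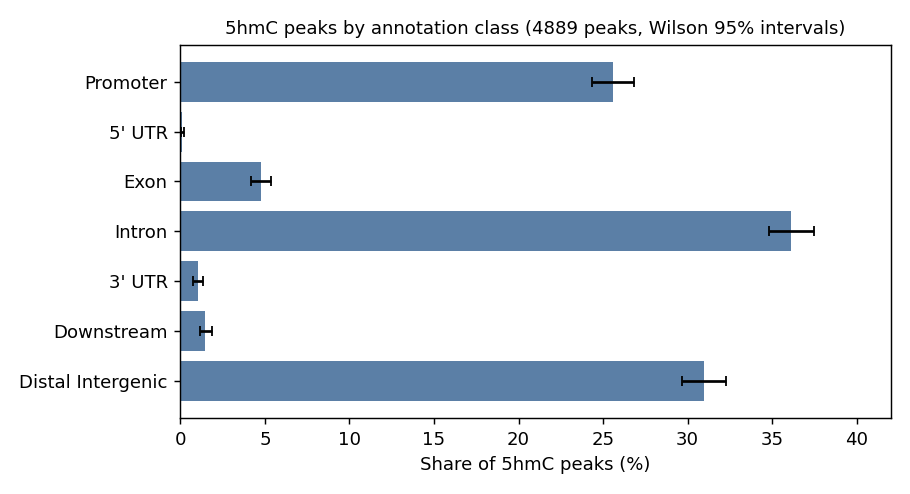
Share of the 4889 5hmC peaks (x axis, %) in each annotation class of the authors' table (y axis), with bars for the share and lines for Wilson 95% intervals. Introns (36.1%), distal intergenic sequence (31.0%) and promoters (25.6%) held most peaks.

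Relative to random positions, peaks lay more often in and next to protein-coding genes. Of the 4459 autosomal peaks, 2278 (51.1%, 49.6 to 52.6) had their midpoint inside a protein-coding gene span, against 42.4% of random placements on the same chromosome (central 95% range 41.0 to 43.8). The share within 1 kb of either end of such a span was 6.93% (6.22 to 7.71), 2.49 times the random share of 2.79%. None of 1000 placements reached either value. Against placements within 50 kb of each peak, the differences were smaller, at 51.1% against 48.8% inside spans and 6.93% against 4.76% within 1 kb of their ends, and again none of 1000 placements reached the observed values. In stricter subsets the local excess inside spans was smaller: 47.6% against 46.5% among peaks at or above the median −log10 q (46 of 1000 placements as high), and 51.6% against 50.7% among those at or above the upper quartile of fold (166 of 1000). The excess also shrank in peaks with at least 10 fragments, a subset chosen after seeing the data. There 44.1% lay inside spans, against 41.6% on the same chromosome (range 39.3 to 43.9) and 42.4% within 50 kb (41.04 to 43.7, 9 of 1000 as high). Their share within 1 kb of span ends was 3.64%, against 3.99% in placements within 50 kb.

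**Figure D3:**
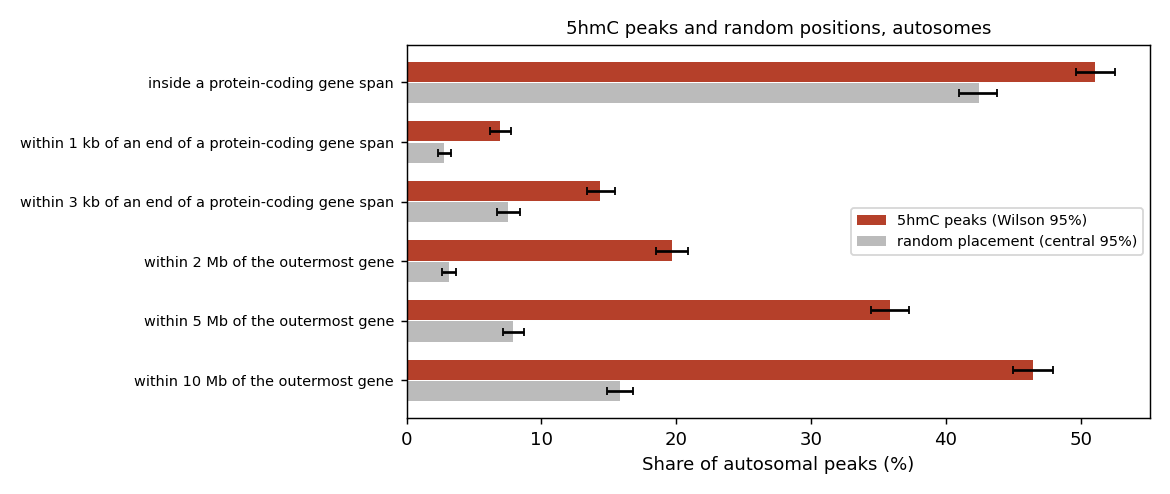
Share of the 4459 autosomal peaks (x axis, %) with a midpoint in the named position (y axis) in red with Wilson 95% intervals, beside the mean and central 95% range of 1000 random placements on the same chromosome in grey. The red bars exceed the grey ones in all 6 positions, including 51.1% against 42.4% inside spans and 35.8% against 7.90% within 5 Mb of the outermost gene.

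The highest fold within 1 kb of a TSS was 9.49, against 16.99 over all peaks, with overlapping intervals. The highest TSS-proximal folds belonged to LOC105378541 (9.49-fold, 5.83 to 14.7) and to ZSCAN22, a zinc-finger gene, and AGPAT3, which encodes a lipid acyltransferase (both 9.47-fold, 5.56 to 15.2). LOC100418696 (9.13-fold), HPN-AS1 (8.39-fold), LOC112267947 (7.99-fold), NEK4P2 (7.83-fold), PLK5 of the polo-like kinase family (7.71-fold), SPPL2B, which encodes an intramembrane protease (7.64-fold), and LINC01605 (7.58-fold) made up the rest. Over all peaks, promoter and distal intergenic peaks had similar folds. The median was 5.01 in promoters (quartiles 4.32 and 5.78) and 5.00 in distal intergenic sequence (4.20 and 5.87). The difference of 0.01 lay inside the central 95% of 10000 shuffles of the class labels (−0.05 to 0.05). Among peaks with a background of at most 2 fragments, tied folds put both medians at 5.22. The difference of 0 there, with a shuffled range of 0 to 0, decides nothing. The difference in mean log2 fold over all peaks was −0.01 (shuffled range −0.03 to 0.03). In 3 stricter subsets, each selected on a quantity tied to the fold itself, the differences lay below the shuffled ranges, at −0.13 among the 2456 peaks at or above the median −log10 q (range −0.11 to 0.09), −0.10 at or above the upper quartile of fold (−0.08 to 0.06) and −0.46 with at least 10 fragments (−0.45 to 0.48). Other pairs of classes were not compared.

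Chromosomes 1 (397 peaks, exact Poisson 95% interval 359 to 438) and 2 (358, 322 to 397) held the most peaks, followed by 7 (270), 10 (267), 16 (257) and 21 (256, 226 to 289). Per Mb between the first and the last gene, chromosome 21 was densest (5.48 peaks, 4.83 to 6.20), ahead of chromosome 19 (4.25, 3.74 to 4.81). Counting peaks with a background of at most 2 fragments, it fell behind chromosomes 19 (3.67 per Mb) and 22 (3.17), at 2.85. The lengths used include assembly gaps, which were not removed, so the order of chromosomes by density is not resolved. Of the peaks on chromosome 21, 119 lay in its first 14 Mb, with a median fold of 2.99 and a median background of 15.02 fragments. The other 137 had a median fold of 5.22 and a median background of 0.791. Chromosomes 18 (94 peaks, 76.0 to 115), 14 (102) and 13 (107) held the fewest.

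The 10 genes with most assigned peaks were mostly noncoding genes or pseudogenes. LOC105375613 on chromosome 7 had 20 assigned peaks (12.2 to 30.9) with a median fold of 5.22. CHEK2P2 on chromosome 15 had 15 (median fold 4.00, median background 4.01). LOC101927209, LOC105379417, LOC100286895 and LOC100287610 had 14 each, with median folds between 1.91 and 3.17 and median backgrounds between 13.5 and 39.3 fragments. LOC100418759 had 13, LOC105378602 and LOC107987293 had 11 each, and LOC101929814 had 10 (median fold 1.88, median background 84.4). Without peaks of a background above 2 fragments and off chromosomes 1 to 22 and X, LOC105375613 (15 peaks), LOC100418759 (12) and CDH4 (9) led.

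Assignment and position often named different genes. Of 1994 peaks in a named intron or exon, 996 (49.9%, 47.8 to 52.1) were assigned to a gene other than the one that held them. Of all peaks, 2083 (42.6%) were assigned to a protein-coding gene, 1287 (26.3%) to a long noncoding RNA gene and 716 (14.6%) to a pseudogene. Counts of genes are therefore given by assignment and by position. By assignment 1482 of 19974 protein-coding genes (7.42%) had a peak, and by position 1861 (9.32%).

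Contractile smooth muscle genes carried peaks about as often as other genes of their length. By assignment 3 of 32 had one, against a mean of 2.80 in length-matched random lists, of which 53.2% held as many. MYL9, the regulatory light chain of smooth muscle myosin, had a peak 0.587 kb upstream of its TSS (chromosome 20, 36540809 to 36540932) of 6.52-fold (3.34 to 11.8, 9 fragments). MYLK, the kinase that phosphorylates this light chain, had one in an intron of 4.41-fold (2.01 to 8.85, 6 fragments). By position 6 of 32 had a peak (random mean 4.07, 21.01% with as many), adding introns of ACTN1, which encodes an actin crosslinker (6.38-fold), CACNA1C, the pore subunit of the L-type calcium channel (5.15-fold, 3 peaks), and SRF, a transcription factor of contractile genes (4.48-fold). ACTA2, MYH11, TAGLN, CNN1 and MYOCD had no peak in the list by either rule.

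Genes of the modulated, matrix-producing state did not stand apart either, with 2 of 34 by assignment (random mean 2.75, 77.4% with as many) and 4 of 34 by position (random mean 3.76). MMP14, a membrane-bound matrix protease, had 2 peaks, the higher in its 3′ UTR (5.82-fold, 2.88 to 10.8). COL15A1 had an intronic peak of 5.17-fold (2.47 to 9.97). By position, COL4A2, a basement membrane collagen gene, held a peak in intron 4 of 8.99-fold (5.99 to 13.02, 26 fragments), and COL5A1, a fibrillar collagen gene, held 6 peaks of up to 6.76-fold. COL4A2 and COL5A1 lie within 5 Mb of the outermost gene of their chromosome, in zones where peaks were denser. So do other list members named above or below, among them CACNA1C, D2HGDH, KDM5A, AKT1, ULK1, SKI, LFNG, NOTCH1, FLT4, LY6H and RBFOX3. Random lists were not matched on these zones, except in a check of the neuronal list. KLF4, SPP1 and LGALS3 had none.

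In the list of DNA methylation genes 1 of 21 had an assigned peak (random mean 1.60, 81.4% with as many), and 3 of 21 had one by position (random mean 2.03). The assigned peak lay 2.42 kb upstream of MBD1, which encodes a methyl-CpG binding protein (6.27-fold, 3.30 to 11.1). D2HGDH, an enzyme that removes D-2-hydroxyglutarate (6.34-fold), and UHRF1, which helps maintain DNA methylation (5.00-fold), held the others. TET1, TET2 and TET3, which encode the enzymes that make 5hmC, had no peak in the list by either rule. Among the genes of histone H3 lysine 4 methylation, the theme of the study's title, 2 of 25 had an assigned peak (random mean 1.99, 60.2% with as many) and 3 of 25 had one by position (random mean 2.71). These were the methyltransferase gene SETD1B with 3 peaks of up to 6.27-fold (3.21 to 11.3), the demethylase gene KDM5A with 1 intronic peak (5.22-fold, 2.49 to 10.1) and, by position, CXXC1, which shares the peak near MBD1.

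The mTOR pathway showed how far the 2 rules can part. By assignment 0 of 36 members had a peak (random mean 2.85, and 5.25% of random lists also had 0). By position 3 of 36 did (random mean 3.89, 76.4% with as many). RPTOR, which encodes the mTORC1 subunit raptor, held 11 peaks within its span on chromosome 17 (80544838 to 80966368). The highest lay in intron 10 (7.89-fold, 4.55 to 12.9, 14 fragments) and was assigned to LOC101928855. RPTOR lies within 5 Mb of the outermost gene at the right end of chromosome 17, a zone with 8.68 times the peak density of the interior. The 11 peaks were not compared with that density. AKT1 (4.59-fold) and ULK1 (4.00-fold) held 1 exonic peak each. For the TGF-beta and BMP pathway the counts were 0 of 32 by assignment (random mean 2.75, 5.69% also with 0) and 1 of 32 by position (random mean 3.91), in an intron of SKI, a repressor of SMAD signalling (5.66-fold).

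Among the signalling lists, the Notch pathway had the highest share of members with a peak. By both rules 4 of 20 had one (random mean 1.51 by assignment and 1.99 by position), and 5.79% and 12.6% of random lists held as many, so the excess was within the range of random lists. HEY2, a Notch target transcription factor, had an exonic peak (5.87-fold, 2.91 to 10.9). NOTCH3, a Notch receptor of vascular smooth muscle, had one 2.59 kb into the gene (5.22-fold, 2.49 to 10.1). LFNG, a glycosyltransferase that modifies Notch receptors (4.52-fold), and NOTCH1 (4.50-fold) had the others. Of 29 adhesion and integrin genes, 4 had an assigned peak (random mean 2.77, 30.8% with as many) and 7 held one by position (random mean 4.36, 13.1%). The assigned ones were TNS1 (6.88-fold, 3.72 to 11.9, 3 peaks) and TNS3 (5.74-fold), which encode tensins, the focal adhesion gene LPP (4.57-fold) and the collagen receptor gene ITGA11 (4.50-fold).

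Markers of other cell types, neuronal genes aside, lay inside the random range. By assignment, peaks belonged to 3 of 25 endothelial genes (PECAM1 at 5.66-fold, FLT4 at 5.50-fold and ICAM2 at 4.41-fold; random mean 1.91) and to 0 of 25 leukocyte genes (random mean 1.73). They belonged to 1 of 20 members of the fibroblast and adventitial list (LY6H, 6.52-fold, random mean 1.49). Whether LY6H marks these cells was not checked. Of 26 cardiac and skeletal muscle genes, 2 had an assigned peak (RYR1, 4.36-fold, and MYBPC3, 4.00-fold, random mean 1.78). The peak assigned to MYBPC3 lies in an intron of SPI1, a gene of the leukocyte list, and counts for SPI1 by position. HOX genes (1 of 39, HOXC12, 4.57-fold; random mean 2.25) and ribosomal protein genes (1 of 48, RPS7, 6.11-fold; random mean 2.79) lay inside the random range as well. By position the counts were 4 of 25 endothelial, 2 of 25 leukocyte, 1 of 20 fibroblast, 1 of 26 cardiac and skeletal, 1 of 39 HOX and 0 of 48 ribosomal protein genes, all inside the central 95% of random lists.

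Neuronal genes were the exception by position. By assignment 5 of 25 had a peak (random mean 2.43, 9.11% with as many). By position 10 of 25 did, against a random mean of 3.81, and 0.19% of random lists held as many (1.44% when matched on finer length bins and on nearness to chromosome ends). It was 1 of 15 lists examined under 2 rules. Those with assigned peaks were the splicing regulator genes RBFOX3 (8.69-fold, 4.92 to 14.4, 4 peaks) and RBFOX1 (7.33-fold, 3.97 to 12.6, 3 peaks), the scaffold gene DLG2 (5.87-fold), the synaptic adhesion gene NRXN3 (5.22-fold) and GAD1, which encodes an enzyme of GABA synthesis (5.00-fold, 3 peaks). Over all 437 genes of the 15 lists together, 29 had an assigned peak (random mean 33.4, central 95% range 23 to 45) and 50 held one by position (random mean 43.5, range 32 to 56).

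**Figure D4:**
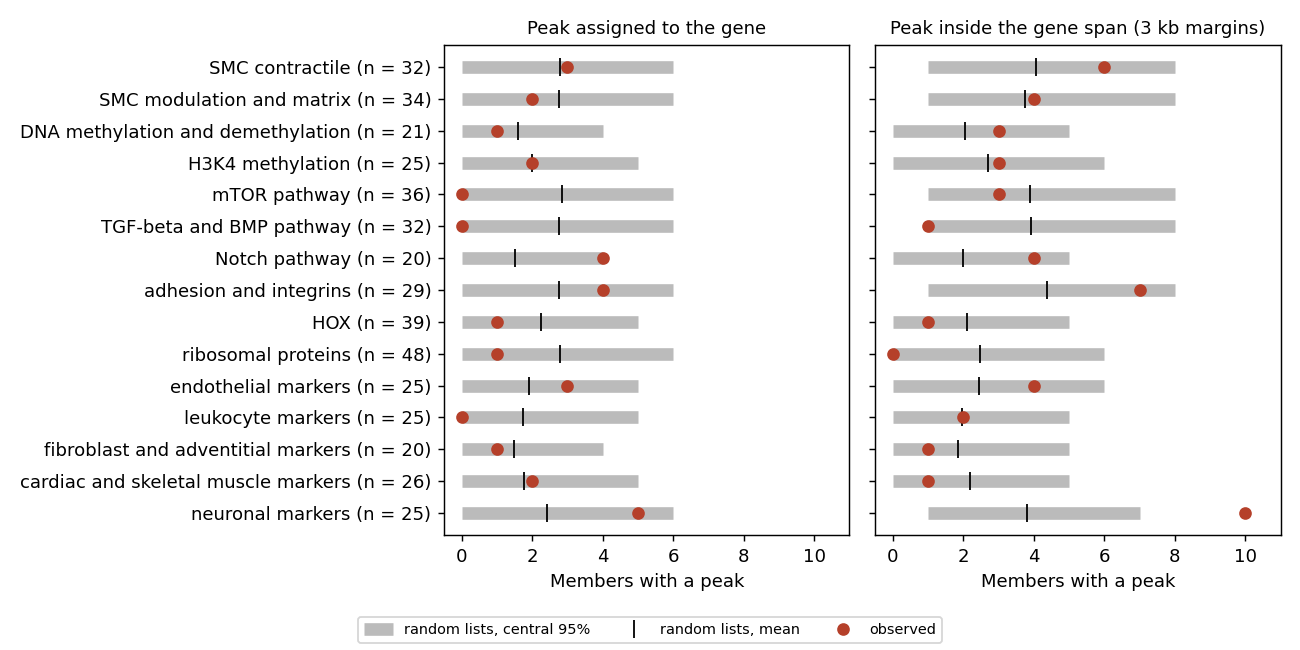
Number of members with a 5hmC peak (x axis) in each of the 15 fixed gene lists (y axis, list size in brackets), by the authors' assignment (left) and by position inside the gene span (right). Red points are observed numbers, ticks the mean and grey bars the central 95% range of 10000 length-matched random lists; the neuronal list by position (10 of 25) is the point to the right of its bar.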

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

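All tests in this part were chosen after the values had been seen, and mitochondrial and low-fold nuclear peaks were joined into 1 pattern after both had been looked at separately. The peak list contained 19 peaks on the mitochondrial genome and 78 on the unplaced contigs KI270733v1 and GL000220v1. They entered the shares by class and TSS distance but none of the comparisons by chromosome or random placement, and are listed here as signal outside those comparisons. Of the 78, 40 were assigned to ribosomal RNA genes or the microRNA genes beside them. The 78 had a median fold of 3.14 and a median background of 16.8 fragments, against 5.16 and 0.759 on the autosomes.

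Mitochondrial peaks had the lowest fold of the list and very high pile-ups, from 160 to 209 fragments, with folds between 1.55 and 2.00, but autosomal peaks also reached 209 fragments in the IP and 209 in the input, with folds down to 1.62. Solved backgrounds above 2 fragments were whole multiples of 0.5007 (within 0.03 of a step) in 83.9% of 911 peaks, so 1 input fragment may have counted as 0.5007. If fragments span 106 bp, the shortest peak width, and 1 read per position and strand is kept, no pile-up can exceed 212. The span of 106 bp is an assumption, since the labels give DNA sheared to 200 to 500 bp. The highest pile-ups were 209 in the IP and 211 in the input. The input of 100% of the mitochondrial peaks lay between 80% and 100% of the ceiling of 212. The IP of 6 of the 19 lay below that range, so a ceiling on both libraries is not shown for all of them. Of the 249 peaks under 3-fold, 90.4% had a background over 10 fragments, against 2.13% of the other peaks, but a peak under 3-fold needs a background of at least 3.67 to reach the lowest deposited −log10 p (4.34), so this split says nothing on whether such sequence has more copies than the reference holds, which stays open. With both libraries at the ceiling the fold would be 1.99 with no enrichment, and the highest mitochondrial fold was 2.00, so more 5hmC on mitochondrial DNA than in the input cannot be told apart from the ceiling; no biological explanation was tested, since the design has 1 condition.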

How the results depend on the processing

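Of 73 alternatives to the main results, 40 stayed within tolerance (1.5 times for counts, the 95% interval for shares, the same side of the shuffled range for the fold difference), 30 moved further and 3 turned the sign of the fold difference to outside its shuffled range; the cause was not tested except where fewer peaks remain by construction. The subsets used were the peaks at or above the median −log10 q, those at or above the upper quartile of fold, those with a pile-up of at least 10 fragments, those with a background of at most 2 fragments, and peaks merged within 1 kb; the subsets by pile-up and background, and all alternatives for the shares inside gene spans and near chromosome ends, were chosen after seeing the data. The number of peaks fell from 4889 to 2456, 1348 and 2115 by q, by fold and at high pile-up. The promoter share moved from 25.6% to 21.8% by fold, 23.8% at low background and 13.7% with promoters of 1 kb. The share within 1 kb of a TSS moved from 13.7% to 10.2% by fold, 12.4% at low background and 12.5% at high pile-up. The share of autosomal peaks on chromosome 1 moved from 8.90% to 9.94% by q, 8.02% by fold, 7.86% at low background and 10.3% at high pile-up. The promoter minus distal difference in median fold turned from 0.01 to −0.13 by q, −0.10 by fold and −0.46 at high pile-up; as a mean of log2 fold it was −0.01, a change of sign inside the shuffled range that is counted among the 40. List genes with an assigned peak went from 29 to 14 by q, 10 by fold and 5 at high pile-up, the last below the central 95% of random lists (mean 11.6, range 6 to 18, 2.32% as few), and to 13 with promoter peaks only and 50 by position. The most peaks of any gene went from 20 (LOC105375613) to 12 by q (CHEK2P2), 8 by fold (LOC105377619), 12 after merging (LOC105375613) and 15 at high pile-up (CHEK2P2), and by density SCNN1D led with 25.9 peaks per 100 kb, from 3 peaks. The share inside protein-coding spans moved from 51.1% to 47.6% by q, 54.8% at low background and 44.1% at high pile-up. The share within 5 Mb of the outermost gene moved from 35.8% to 38.6% by q, 41.5% by fold and 42.6% at high pile-up; it was 19.7% within 2 Mb and 46.5% within 10 Mb. Of 285 alternatives for single lists, 274 kept the list on the same side of the 2.5% limits; 9 of the other 11 concerned the neuronal list by position, and 2 concerned the adhesion and ribosomal lists without length matching. No paired analysis was possible because there was 1 library per group, and no replicate could be left out. Rebuilding classes and TSS distances from the reference was not run, since the gene table has no strand or exons, and the sequence content of peaks was not run without a genome. The depth of each library is unknown, and low pile-ups limit the precision of single folds (43.3% of peaks had at least 10 fragments).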

Other observations

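Some protein-coding genes held many peaks by position; they were chosen after their values were seen. PTPRN2, which encodes a receptor-type phosphatase of secretory granules, held 44 peaks within its span on chromosome 7 (157539056 to 158587823; exact Poisson 95% interval 31.97 to 59.1), the most of any protein-coding gene of at least 10 kb. LOC105375613, the gene with the most assigned peaks, has its peaks inside this span. CDH4 held 16 peaks (9.15 to 26.0), ADARB2, of the RNA-editing deaminase family, held 14 (7.65 to 23.5), and MAD1L1, a spindle checkpoint gene, RPTOR and TTC34 held 11 each. COL18A1, the gene of the basement membrane collagen that yields endostatin, held 9 peaks in 109 kb (8.29 per 100 kb) of up to 10.4-fold. The mucin gene MUC2 held 8 peaks in 35.6 kb. All the genes named in this paragraph lie within 5 Mb of the outermost gene of their chromosome, where peaks were denser, as given below. Their counts were not compared with the density of those zones, so they cannot be read as particular to these genes.

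In the rest of this part, the test of repeated sequence at chromosome ends was chosen after its result had been seen, and the tests of gene density and of the neuronal list were set before theirs. Of 4459 autosomal peaks, 1598 (35.8%, 34.4 to 37.3) lay within 5 Mb of the outermost gene, against 7.90% of random placements (7.13 to 8.70), and 34 of 39 ends were denser than the interior of their chromosome, with a median ratio of 7.41. The right end of chromosome 13 (52 peaks, 20.7 times the interior density) and the left end of chromosome 5 (62 peaks, 19.2 times) led, while the left ends of chromosomes 3 (0.352 times) and 9 (0.359 times) were among the 5 below their interior. Interior lengths include assembly gaps, which were not removed and raise these ratios, so the order of the ends is not resolved. More genes near the ends were not enough, since 13.2% (12.7 to 13.6) of protein-coding genes had their middle in these zones. For repeated sequence, the test set first compared peaks with a background over 2 fragments and decided nothing (14.02% in the zones, 16.3% elsewhere). Its replacement was the share of low-background peaks (at most 2 fragments) in the zones, 36.5% against 7.91% at random. This filter kept 3768 of the 4459 peaks, so that share had to stay above the random range wherever the removed peaks lay. Peaks of higher background are thus too few to make up the whole excess. Repeats with a lower background were not tested. CpG density, GC bias and tandem repeats stay open because no sequence was used here, and no biological explanation was tested.

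By position, the neuronal list was the only one of the 15 outside the central 95% of length-matched random lists; by assignment none was. Its members had a median length of 156 kb, and 4 of the 25 lie within 5 Mb of the outermost gene. With 50 length bins, 0.43% of random lists still held 10 members with a peak (random mean 4.42), and with the end zone matched as well, 1.44% did (random mean 5.21). Length and nearness to chromosome ends may therefore account for part of the excess. Whether they account for all of it is not settled, because bins cannot match the longest genes closely. RBFOX1, at 2474 kb, is itself the longest gene in the comparison. Any remaining excess is a weak hypothesis, since 1.44% in 1 of 15 lists under 2 rules does not survive an allowance for their number, and CpG content was not tested.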
